A study of Drosophila melanogaster with 28 samples.

How the data were processed

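RNA sequencing of Drosophila melanogaster was analysed in 28 libraries. Per the labels, flies were kept at 25 °C and fed yeast paste, total RNA was taken with TRIzol, 5 ug were depleted of ribosomal RNA with Ribo-Zero Gold, and libraries were made with ScriptSeq V2. Gene expression was measured in 8 libraries, with 2 replicates each of OSS cells, ovary, carcass and 0 to 2 h embryo. Transposon families were measured in 22 libraries, which are the same 2 ovary libraries, 2 libraries of the nos-GAL4 knockdown of w and 1 library each for knockdowns of 18 genes. Groups were taken from the labels. Knockdowns with the somatic driver tj-GAL4, named in the design text, were not analysed here.

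The deposited gene values are FPKM, fragments scaled to transcript length and to the mapped total, made by the authors per gene symbol. The submitters' processing notes name CASAVA 1.3, Bowtie, TopHat, Cufflinks and the genome build dm3, and the annotation and filters are not given in the sources used here. The values of carcass replicate 1, although named FPKM by the authors, were recorded under the unit other, because 1070 of its 14147 lines hold no number (1068 are blank and 2 hold the text OK), and 5 lines of carcass replicate 2 hold dashes. Those lines were treated as missing. The deposited transposon values are whole numbers per family, recorded here as a score whose unit is not given in the sources used here. They behave like reads scaled to a fixed number of genome-mapped reads and rounded by the authors. Between the 2 ovary libraries their variance over 125 families of low value was 0.499 of what counting would give if they were raw counts, although the libraries hold 11395525 and 6733164 genome-mapped reads, and it was 2.70 between the 2 w libraries over 110 families. How reads were assigned among families, and with which strand and mapping rule, is not given in the sources used here.

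Genome-mapped reads numbered 10600469 for the armi knockdown, 5600186 for ars2, 4929854 for aub, 2429481 for CG3893, 4922424 for cuff, 8092276 for del, 2026093 for gasz, 3670595 for mael, 6302378 for piwi, 7550277 for rhi, 5141370 for shu, 5770014 for spn-E, 3329553 for squ, 20185962 for tej, 6468663 for U2A, 4571353 for vasa, 3831461 and 3037471 for w, 4535939 for Yb and 6176815 for zuc. At this depth a score of 10 in the gasz library rests on few reads, and no counting intervals are given because the unit is inferred. FPKM summed to between 459357 and 629055 per library, and the read totals behind them are unknown. Lines at 0 numbered 2166 and 2640 in OSS, 2098 and 3184 in ovary, 2514 and 1751 in carcass and 5479 and 3920 in embryo.

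Genes were joined between libraries by name. The 93 names found on more than 1 line (255 lines) were left out, which left 13892 genes. Genes with an FPKM of 1 or more in at least 2 libraries were tested, 11488 in all, on log2(FPKM + 1). Because of the pseudocount of 1, log2 differences of genes at low FPKM are understated, and no fold is given against a group listed at 0. Of 176 transposon families, 53 are named for other Drosophila species, and the gasz library lists 175. Families with a score of 10 or more in at least 2 libraries were kept, 159 in all, 40 of them named for other species, on log2(score + 1). Values were used as deposited, without further normalization. The gene files name several genes by older symbols, which are kept here: CG5508 for mino, CG31755 for SoYb, CG7082 for papi, CG9754 for Panx, CG8920 for tapas, CG2183 for gasz, CG3893 for arx and sop for RpS2. Positions are not given, because the annotation at hand is for another build than dm3.

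The tissue groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) in 1 fit over all 8 libraries with 4 residual degrees of freedom, for ovary minus carcass, ovary minus OSS and embryo minus ovary. Calls are Benjamini-Hochberg adjusted p under 0.05, and all limma tests are 2-sided. Replicate numbers were not used as a block, because deviations of equal numbers in different groups were not correlated (-0.07 to 0.02 between tissue groups and 0.044 between w and ovary for transposon families). Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over 45 tests. camera used only genes with a value in all 8 libraries, so a list can be smaller there than the size given next. The lists were germline piRNA genes (27 tested), somatic piRNA genes (2), siRNA and microRNA genes (9), maternal germline genes (29), ovarian somatic markers (21), eggshell genes (18), early zygotic genes (16 of 29), muscle (21), fat body (15), gut (19), neuron and eye (19) and immune genes (19), DNA replication and cell cycle genes (19), ribosomal protein genes (25) and the genes targeted in the knockdowns (19). The transposon lists were germline (20 families), somatic (12), telomeric (HeT-A and TAHRE), LTR (59), non-LTR (36) and DNA families (22). The family aurora-element is in both the LTR and the non-LTR list. Tc1-2, named like the DNA family Tc1, is in the non-LTR list, so counts by type follow the lists as written. Lists, classes of knocked-down genes, tests, thresholds and the alternatives were chosen before the data were examined, except where stated otherwise.

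Each single knockdown was compared with the mean of the 2 w libraries on the log2 scale without a test. The 15 pathway knockdowns were compared as 1 group with w, each of 4 classes with the mean of the other 3 classes, and w with ovary, by limma. Class labels were permuted 100000 times for the germline median and for the similarity of profiles, with a range or a difference of means as the statistic. The similarity test is 1-sided, for pairs of a class being more alike. Pearson and Spearman coefficients across libraries have permutation p-values from 100000 draws, 2-sided. Medians of lists were set beside those of 10000 random lists drawn within 5 bins of mean level. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. The p-values measure only the spread between the libraries at hand. In the class comparisons that spread is between knockdowns of different genes.

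Genes named in the text follow a fixed rule. For tissues these are the 5 genes with the highest and the 5 with the lowest log2 difference among those called with no overlap between the groups, the members of each list with the 2 largest and the 2 smallest differences, and every targeted gene. For transposons these are the 3 families with the largest difference per knockdown, the 5 highest and 5 lowest called per limma comparison, and always the telomeric list, Burdock, blood, gypsy and ZAM. Genes and families outside the rule were chosen after their values were seen, among them smg, nos, exu, pgc and osk in embryo minus ovary, tj in ovary minus OSS, R2-element, Rt1c, Bari1, Dnet_R1A, Tirant, the cluster class families invader4, Rt1a, accord2, diver2, Cr1a, X-element, Circe, gypsy2, mdg1 and pogo, and families compared across knockdowns where they were not among the 3 largest. Families whose whole name is a number, and snmRNA genes, which are known by a number, are not named in the text. The count of knockdowns with a germline median of at least 2-fold was also chosen after the data were seen.

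Alternatives were a pseudocount of 0.1 (genes) and of 0.1 and 10 (families), no filter and stricter filters of 5 (genes) and 100 (families), quantile normalization, median-ratio scaling, scaling of transposon values to 1 median over families, a replicate block, a 2-fold minimum, other controls, mael moved to the nuage class, and leaving out each library in turn. A fit with families of melanogaster name only was added after seeing the data. For a left-out library in a group of 2, the remaining library is assumed to vary like the other groups. Each class count was also set against 100 splits of the 15 libraries into groups of the same sizes.

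The fits were tested on simulated data. With 200 changed genes among 9034 in a simulated ovary and carcass comparison, 51% of 2-fold and 92% of 4-fold changes were recovered with 6 false calls. The real comparison called 8567 of 11488 genes, so these rates describe a setting with far fewer changed genes. With 40 changed families among 159, the simulated comparison of 15 with 2 libraries recovered 71.9% of 2-fold and 99.9% of 4-fold changes, with 1.15 and 2 false calls on average, and the simulated cluster class 83.4% and 99.9%, with 1.25 and 1.95 false calls. In the real comparison with w, HeT-A had a log2 difference of 3.14 (SE 1.14) and was not called by limma (adjusted p = 0.154). The simulated recovery therefore does not hold for families that vary strongly between knockdowns. In 20 simulated sets without an effect the permutation tests of the germline median and of similarity made 1 and 2 calls, and in 20 with an effect 19 and 20 calls.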

Results

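RNA was profiled in 28 libraries of Drosophila melanogaster, made from total RNA depleted of ribosomal RNA, in a study of genes that silence transposons in the ovary through the piRNA pathway, in which small RNAs bound to PIWI proteins guide the silencing. In 8 libraries gene expression was measured in 4 groups of 2 replicates: OSS, a cultured line of ovarian somatic sheet cells without germline; whole dissected ovaries; the carcass left after the ovaries had been removed; and embryos aged 0 to 2 h. In 20 further libraries the abundance of transposon families was measured in ovaries in which nos-GAL4, a driver active in the germline, expressed double-stranded RNA against 1 gene. These covered 18 genes with 1 library each and the control gene w, an eye pigment transporter, with 2 libraries. The 2 ovary libraries were also measured for transposon families. Genome-mapped reads in the transposon libraries ranged from 2026093 (gasz) to 20185962 (tej), with 3831461 and 3037471 for the 2 w libraries. The gene values are FPKM, whose read totals are not given in the sources used here, so the depth behind single genes is unknown. Genes at an FPKM of 1 or more numbered 9396 and 9274 in OSS, 8536 and 8344 in ovary, 9733 and 10997 in carcass, and 6818 and 8071 in embryo. The level of each targeted gene in its own knockdown was not analysed here, because the knockdown values cover transposon families, so the labels of these libraries were not checked on the target.

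The levels of the targeted genes in the tissue libraries were examined first. In ovary, vas, a DEAD-box helicase of the perinuclear nuage, was the most abundant at an FPKM of 168 ± 1.03 (SD, n = 2, as for all means of tissue groups), followed by squ at 130.3 ± 2.97 and Ars2 at 107 ± 1.06. The least abundant were cuff at 10.4 ± 2.22 and fs(1)Yb (the Yb target), which acts in ovarian somatic cells, at 0.984 ± 0.390. In OSS, fs(1)Yb reached 49.0 ± 0.575, armi 227 ± 5.84 and piwi 197 ± 10.3, whereas vas was at 3.05 ± 0.132 and tej at 2.42 ± 0.456. The control target w was at 64.4 ± 2.24 in ovary and 51.4 ± 3.05 in carcass.

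**Figure D1:**
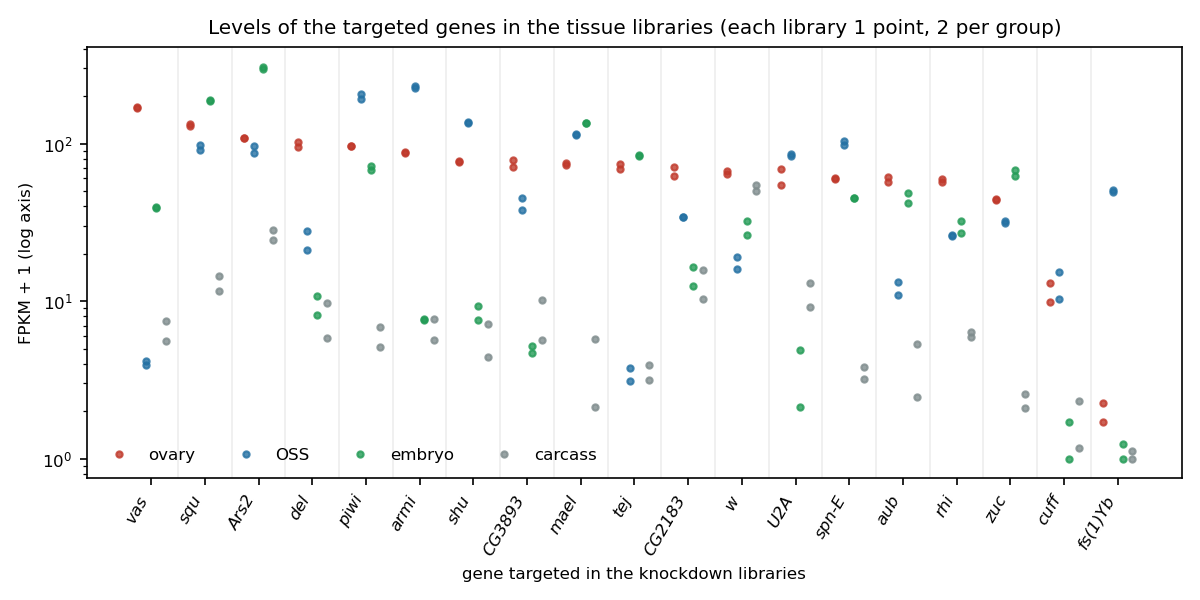
FPKM plus 1 on a log axis (vertical) of the 19 genes targeted in the knockdown libraries (horizontal), with 1 point per library and 2 libraries each of ovary, OSS, embryo and carcass. In OSS fs(1)Yb averages 49.0 against 0.984 in ovary, and vas averages 168 in ovary against 5.55 in carcass.

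Ovary and carcass were compared to find transcripts that are more abundant in the ovary than in the rest of the female body. Of 27 germline piRNA pathway genes tested, 26 rose. CG5508 (minotaur) was not called, at a log2 difference of -0.03 (SE 0.18, adjusted p = 0.904). The helicase vas was at 168 ± 1.03 in ovary and 5.55 ± 1.34 in carcass, a log2 difference of 4.70 (SE 0.17, adjusted p = 2.89e-06), and piwi, the PIWI protein that acts in the nucleus, differed by 4.02 (SE 0.15, adjusted p = 3.21e-06). The piRNA genes mael, tej and spn-E rose by 4.40, 4.34 and 4.10, and zuc, the nuclease that forms piRNA ends, by 4.24. Among 29 genes of the maternal germline 27 rose, led by plu, a regulator of the first embryonic cycles, with 4.88 (SE 0.25, adjusted p = 6.42e-06) and stil with 4.73. The exceptions in this list were grk, which encodes the oocyte's EGF receptor ligand, at 0.28 (SE 0.22, adjusted p = 0.283), and bgcn at 0.37 (SE 0.27, adjusted p = 0.249). All 18 eggshell genes tested rose, among them the chorion genes Cp15, at 2067 ± 108 in ovary and 7.85 and 57.1 in the 2 carcass libraries, and Cp18, with a difference of 7.05 (SE 0.97, adjusted p = 0.000445). All 19 genes of DNA replication and the cell cycle rose as well, such as the replicative helicase subunits Mcm3 by 4.44 and Mcm7 by 4.42. The 2 genes tested of the somatic piRNA list, CG31755 (SoYb) and fs(1)Yb, differed by 3.60 (SE 0.15, adjusted p = 4.07e-06) and 0.90 (SE 0.28, adjusted p = 0.0211). The call for fs(1)Yb was lost without ovary replicate 1 (0.70) and without carcass replicate 1 (0.82), and with median-ratio scaling (0.66). Of 9 genes for siRNAs and microRNAs 8 rose, among them pasha by 2.30 and Dcr-2 by 1.92, and AGO2 stood at 0.05 (SE 0.08, adjusted p = 0.567).

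Markers of other tissues were lower in the ovary. All 21 muscle genes fell, with troponin C genes at the extreme, TpnC41C at 2.75 ± 0.746 in ovary and 579.8 ± 54.4 in carcass and a log2 difference of -7.29 (SE 0.22, adjusted p = 2.32e-06). All 19 neuron and eye genes fell, and the opsin ninaE had a difference of -7.83 (SE 0.40, adjusted p = 6.57e-06). Of 15 fat body genes 14 fell, including the storage protein gene Lsp2 (-6.04) and fit (-6.40). Of 19 gut genes 17 fell, including the trypsin gene alphaTry (-7.82). Among 19 immune genes 18 fell, and the peptide gene IM1 had 2925 ± 450.0 in carcass against 13.8 and 22.2 in the 2 ovary libraries. The ovarian somatic list went both ways, with 7 of 21 higher and 6 lower. The transcription factor gene tj rose by 2.53, and the FGF ligand gene bnl had a difference of -3.34. Of 16 early zygotic genes 4 rose and 8 fell, with slam at 3.90 and rho at -3.71, and 4 higher and 5 lower after quantile normalization. Among genes of no list, msd1, a subunit of the augmin complex of the mitotic spindle, averaged 85.6 in ovary and was listed at 0 in both carcass libraries. CG13998 averaged 70.6 and was listed at 0 in the single carcass library with a value. At the other end lay lcs at -8.82 (SE 0.38), Acp65Aa, a cuticle gene, at -8.78 (SE 0.57) and CG13323 at -8.67 (SE 0.55), while CG12158 and CG34212 were listed at 0 in both ovary libraries and averaged 499 and 875 in carcass.

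Of 11488 genes tested with limma, 8567 differed between ovary and carcass at a Benjamini-Hochberg adjusted p under 0.05, 4993 higher in ovary and 3574 lower (58.3% higher), with 3956 and 3275 at least 2-fold. With median-ratio scaling 40.6% of the calls were higher. The median of all genes was 0.31 as deposited, 0.35 after quantile normalization and -0.29 after median-ratio scaling. Ribosomal protein genes followed that shift, with 22 of 25 higher and 1 lower as deposited (RpL4 0.72, RpS5a -0.27), 25 higher and 0 lower after quantile normalization and 0 higher and 17 lower after median-ratio scaling. The call for RpS5a was lost without ovary replicate 1 (-0.21) and without carcass replicate 2 (-0.19). After median-ratio scaling the germline piRNA list had 23 higher and 3 lower, the small RNA list 5 higher and 1 lower and the ovarian somatic list 4 higher and 9 lower (11 higher and 4 lower after quantile normalization). The maternal germline, eggshell, replication, muscle, neuron and eye, fat body, gut and immune lists kept their direction under both. Adjusted over the list alone, the counts were the same except for the immune list (19 lower). camera, a test of a list against all other genes, with a preset correlation of 0.01 gave adjusted p = 4.8e-07 for the germline piRNA list, 1.97e-07 for the maternal germline, 1.45e-08 for replication, 0.00161 for eggshell, 0.0228 for the small RNA list, 0.00661 for ribosomal genes, 5.93e-09 for muscle, 8.7e-09 for neuron and eye, 2.3e-05 for fat body, 2.56e-07 for gut and 1.86e-06 for immune genes. None of these 11 calls held when the correlation was estimated, the lowest being adjusted p = 0.109 with an estimated correlation for replication, then 0.245 for the maternal germline, muscle and fat body, 0.273 for eggshell and for neuron and eye, 0.336 for gut, 0.374 for immune, 0.421 for small RNA, 0.436 for germline piRNA and 0.771 for ribosomal genes. The somatic piRNA (adjusted p = 0.246), ovarian somatic (0.967) and early zygotic (0.217) lists passed neither way. The 19 targeted genes, which overlap the piRNA list and were chosen by the study, had 18 higher (adjusted p = 8.64e-06 by camera and adjusted p = 0.42 with an estimated correlation). Muscle genes in ovary had a median level of 4.46% of that in carcass.

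Ovary was compared with OSS cells to separate transcripts of the germline from those shared with ovarian somatic cells. Maternal germline genes were on the ovary side, with 26 of 29 higher. The posterior determinant osk was at 404 ± 12.6 in ovary and 0.339 ± 0.0637 in OSS, a log2 difference of 8.24 (SE 0.15, adjusted p = 1.02e-06), and gnu, which acts with plu in the first embryonic cycles, differed by 7.56 (SE 0.39). The exception in direction was bgcn at -1.55 (SE 0.27), not called after quantile normalization (-0.85), and grk stood at 0.12 (SE 0.22, adjusted p = 0.712). The germline piRNA list was divided. Of 27 genes 11 were higher in ovary, led by vas with 5.38 (SE 0.17, adjusted p = 4.15e-06) and the PIWI gene AGO3 with 4.49 (SE 0.11, adjusted p = 1.84e-06), followed by tej with 4.39, aub with 2.31 and the cluster gene del with 2.03. In the other direction 5 were higher in OSS, among them armi, a helicase, at 227 ± 5.84 against 86.9 ± 1.32 in ovary with -1.38 (SE 0.16, adjusted p = 0.000685), piwi at 197 ± 10.3 with -1.05 (SE 0.15, adjusted p = 0.00169) and spn-E with -0.74 (SE 0.13, adjusted p = 0.00347). In the somatic piRNA list fs(1)Yb was lower in ovary with -4.67 (SE 0.28, adjusted p = 3.56e-05), and CG31755 was higher with 1.06 (SE 0.15, adjusted p = 0.00144). Of the small RNA list, AGO1, Dcr-2 and 1 other gene of 9 were higher and AGO2 was lower (1.02, 0.94 and -0.94 for the named genes). Among the targeted genes 10 were higher and 5 lower, and w stood at 1.90 (SE 0.15).

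Eggshell genes were higher in ovary without exception, 18 of 18, with Cp38 averaging 1464 in ovary against 0 and 0.375 in the 2 OSS libraries and the smallest difference at dec-1 with 2.77 (SE 0.25). The ovarian somatic list had 5 genes higher and 11 lower of 21, with ptc, the Hedgehog receptor, at -4.42 (SE 0.28, adjusted p = 4.58e-05), tj at -1.74 and wun2 at 2.20. Of 21 muscle genes 15 were higher in ovary (Mf 4.46, up 5.11) and 3 lower (TpnC41C -3.83, sls -1.63). Of 15 fat body genes 8 were higher, and these included the yolk protein genes Yp1 with 7.47 and Yp2 with 7.65, which follicle cells also express. Ribosomal protein genes were lower, 15 of 25 with 1 higher (RpL14 -0.70, RpLP1 -0.74). Replication and cell cycle genes had 6 higher and 3 lower of 19, with CycB at 2.33 and CycE at 1.83. Immune genes had 6 higher and 2 lower of 19 (PGRP-SA -3.30), with 7 higher and 1 lower after quantile normalization. Neuron and eye genes had 2 higher and 5 lower of 19 (norpA 2.22, Rh6 -3.61), with 3 higher and 4 lower after that normalization. Gut genes had 1 higher and 2 lower of 19 (CG30360 -1.75, not called after quantile normalization at -0.87; 3 higher and 0 lower after it), and early zygotic genes 3 higher and 5 lower of 16 (hb 4.61, sc -3.85; 3 higher and 3 lower after quantile normalization). Among genes of no list, dhd, a thioredoxin of the female germline, differed by 9.39 (SE 0.11, adjusted p = 1.81e-07), and CG14072, CG14984 and Her by -8.23 (SE 0.59), -7.84 (SE 0.32) and -6.47 (SE 0.35). Cp19, averaging 889 in ovary, was listed at 0 in both OSS libraries. CG42852 and CG15323 were listed at 0 in both ovary libraries and averaged 280.4 and 304 in OSS.

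limma called 4796 of 11488 genes between ovary and OSS, 2156 higher in ovary and 2640 lower, with 3040 at least 2-fold. The share higher was 45.0% as deposited, 49.0% after quantile normalization and 50.6% after median-ratio scaling. The median of all genes was -0.16, and -0.04 and -0.09 after quantile normalization and median-ratio scaling. The count of 4796 depended on single libraries and was 2879 without OSS replicate 1, 2928 without OSS replicate 2 and 3056 without ovary replicate 2. By camera the lists called were the maternal germline (adjusted p = 2.46e-18), eggshell (2.31e-10), muscle (5.97e-05), fat body (0.000768), ribosomal (0.0012) and immune genes (0.0413). With an estimated correlation none was called, the maternal germline and eggshell lists giving adjusted p = 0.109 with an estimated correlation, muscle and fat body 0.273, ribosomal 0.7 and immune 0.752. The lists not called were germline piRNA (adjusted p = 0.061), ovarian somatic (0.148), replication (0.118), early zygotic (0.439), gut (0.473), neuron and eye (0.714), small RNA (0.325), somatic piRNA (0.862) and the targeted genes (0.118). Adjusted over the list alone, 27 maternal germline, 16 muscle and 7 immune genes were higher, 18 ribosomal and 6 neuron and eye genes were lower, replication had 8 higher and 4 lower, gut had 0 higher, and the other counts were the same.

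Embryos of 0 to 2 h, whose RNA is largely deposited by the mother, were compared with ovaries. Maternal germline genes went both ways, with 9 of 29 higher and 17 lower in embryo. The cyclin gene CycB3 was at 627 ± 25.1 in embryo and 123 ± 4.47 in ovary, a log2 difference of 2.35 (SE 0.09, adjusted p = 1.38e-06), the anterior determinant bcd was at 290.2 ± 1.51 and 70.8 ± 1.53, a difference of 2.02 (SE 0.13, adjusted p = 1.21e-05), and the RNA regulator smg rose by 1.51. In contrast alphaTub67C, the maternal alpha-tubulin, was at 0.636 and 2.76 in the 2 embryo libraries against 208 ± 0.328 in ovary, a difference of -6.40 (SE 0.40, adjusted p = 9.12e-06), gnu differed by -6.33 (SE 0.39, adjusted p = 8.44e-06), and nos, exu, pgc and osk stood at -5.24, -5.05, -5.03 and -2.90. The split was 11 higher and 17 lower after quantile normalization and 11 higher and 16 lower after median-ratio scaling. The germline piRNA genes had 6 higher and 14 lower of 27, a balance that turned to 11 higher and 10 lower after quantile normalization and 15 higher and 9 lower after median-ratio scaling. Lower under each of these were CG3893 (asterix) with -3.92 (SE 0.28, adjusted p = 1.72e-05), armi with -3.52, del with -3.39 and shu, a co-chaperone, with -3.19. The nuage genes tej and aub stood at 0.23 (SE 0.18, adjusted p = 0.333) and -0.40 (SE 0.35, adjusted p = 0.373). Of the 19 targeted genes 3 were higher and 13 lower (5 higher and 9 lower after quantile normalization and 7 higher and 8 lower after median-ratio scaling), with Ars2 at 1.48 (SE 0.10) and U2A at -4.24 (SE 0.39).

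All 18 eggshell genes fell, Cp15 from 2067 ± 108 in ovary to 2.84 and 0 in the 2 embryo libraries, and Cp36 and Vm34Ca were listed at 0 in both. Of 21 muscle genes 19 fell, such as Mf (-5.66), and Tm1, a tropomyosin gene, rose by 1.07. Ovarian somatic genes had 2 higher and 9 lower of 21, with tj at -4.08 (SE 0.25), Fas3 at -3.79 and EcR at 1.25; the list had 6 higher and 4 lower after quantile normalization and 5 higher and 6 lower after median-ratio scaling. Of 15 fat body genes 8 fell, with Yp1 at -7.88, and of 19 immune genes 9 fell (quantile splits of 2 higher and 7 lower and 1 higher and 7 lower). Ribosomal protein genes had 22 lower of 25 and 2 higher, RpS6 with 1.01 and RpL5 with 0.23, against 10 higher and 10 lower after median-ratio scaling. RpLP0 at 32.1 ± 8.44 in embryo and 398 ± 21.1 in ovary and RpL8 were the lowest, with -3.62 (SE 0.16) and -3.15 (SE 0.13). The call for RpL5 was lost without ovary replicate 1 (0.22) or 2 (0.24) and without embryo replicate 2 (0.18). Replication and cell cycle genes had 9 higher and 8 lower of 19 (7 higher and 8 lower after quantile normalization and 12 higher and 7 lower after median-ratio scaling). The genes dup and geminin, which license replication and restrain it, rose by 2.21 and 1.90, and RnrS and Orc2 stood at -4.64 and -4.77. Of the small RNA genes 2 were higher and 4 lower of 9 as deposited and 6 higher and 2 lower after quantile normalization (6 higher and 0 lower after median-ratio scaling), with AGO1 at 1.67. Early zygotic genes, of which 16 passed the filter, had 1 higher, slam with 1.49 (SE 0.18), and 4 lower (5 higher and 3 lower after quantile normalization and 5 higher and 4 lower after median-ratio scaling). Neuron and eye genes had 2 higher, Syx1A with 1.49 among them, and 4 lower of 19 (9 higher and 1 lower after quantile normalization and 7 higher and 1 lower after median-ratio scaling). Of 19 gut genes 4 fell (1 higher and 4 lower after quantile normalization). In the somatic piRNA list both genes were lower as deposited, CG31755 with -0.81 (SE 0.15) and fs(1)Yb with -0.82 (SE 0.28), the latter not without OSS replicate 1 (-0.82), OSS replicate 2 (-0.82), ovary replicate 1 (-0.62) or embryo replicate 1 (-0.67), nor after either rescaling (-0.62 and -0.51). CG31755 stood at 0.55 after quantile normalization and 0.43 after median-ratio scaling. Among genes of no list, CG32374, CG12672, CG31140 and CG14245 rose by 4.20, 4.16, 3.93 and 3.68.

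limma called 6882 of 11488 genes between embryo and ovary, 1732 higher in embryo and 5150 lower (25.2% higher), with 1086 and 4595 at least 2-fold. The share higher was 53.5% after quantile normalization and 47.5% after median-ratio scaling, as the median of all genes moved from -0.58 to 0.18 and 0.00. By camera the eggshell (adjusted p = 0.000482), ribosomal (0.000823) and muscle (0.00207) lists were called, with adjusted p = 0.245, 0.7 and 0.375 with an estimated correlation in the same order, and the other 12 lists were not, their adjusted p lying between 0.111 for neuron and eye and 0.945 for germline piRNA genes. Adjusted over the list alone, the counts were the same except for gut (2 lower), neuron and eye (1 higher) and immune genes (8 lower). Of 3160 genes at an FPKM of 50 or more in both ovary libraries, 134 were listed at 0 in embryo replicate 1 and 87 in replicate 2, so a value of 0 is not read here as absence of the transcript.

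To see which transposon families depend on each targeted gene, every knockdown library was set against the mean of the 2 w libraries on the log2 scale. With 1 library per gene these differences have no replicate check and no p-value, and all of them share the same 2 w libraries. The LTR retrotransposon 3S18, at 141 and 107 in the w libraries and 118 and 104 in ovary, reached 10588 after knockdown of del, 10082 for vasa, 7669 for cuff and 7388 for shu, and stood at 176 for squ and 113 for Yb. HeT-A, a retrotransposon that maintains telomeres, was at 151 and 112 in the w libraries and stood at 8515 for shu, 5631 for piwi, 3450 for zuc and 2794 for CG3893, against 122 for aub, 130 for U2A and 118 for Yb. blood, at 401 and 232 in the w libraries, was at 1777 or more in each of the 15 piRNA pathway knockdowns and at 4467 for U2A, and Burdock, at 80 and 51, reached 3291 for shu and 3282 for del. mdg3 reached 8656 for shu and 4969 for piwi, against 80 for squ. ZAM, a retrovirus of ovarian somatic cells, lay between 54 and 87 in all 20 knockdown libraries.

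Over the 20 families of the germline list, the median log2 difference against w was 2.74 for shu, 2.00 for zuc, 1.96 for piwi, 1.70 for CG3893, 1.62 for mael, 1.49 for armi, 1.46 for gasz, 1.41 for spn-E and 1.37 for both cuff and del. These are the 10 of 18 knockdowns with a median of at least 2-fold. The others lay at 0.79 for vasa, 0.39 for aub, 0.29 for U2A, 0.27 for rhi, 0.20 for squ, -0.00 for tej, -0.03 for ars2 and -0.19 for Yb. Among 10000 random lists of the same size matched on mean level, the germline median stood at the 99.99 percentile or above for these 10, at 98.98 for vasa, 98.65 for tej, 97.14 for rhi, 76.1 for aub, 67.3 for squ, 63.0 for U2A, 26.9 for Yb and 24.3 for ars2, as a description of these libraries. The median over the 12 families of the somatic list ranged from -0.36 for tej to 0.71 for zuc, and the 2 telomeric families HeT-A and TAHRE had medians from -0.13 for Yb to 5.16 for shu. Families at least 2-fold above w numbered 43 of 159 for shu, 42 for zuc and piwi, 31 for CG3893, 28 for gasz, 27 for spn-E, 26 for mael, 24 for cuff, 21 for armi and vasa, 20 for del, 17 for aub, 15 for rhi, 11 for ars2, 9 for U2A, 8 for squ and 6 for tej and Yb. In the tej library 11 families were at least 2-fold below w and the median of all families was -0.29, while in the other knockdowns 0 to 6 families were that far below. For comparison 11 families differed at least 2-fold between the 2 w libraries and 0 between the 2 ovary libraries; the largest difference between the w libraries was 2.92 for Rt1c (652 and 85) and the median absolute difference 0.42. The median of the germline list was 0.39 higher in w replicate 1 than in w replicate 2. Across the 15 pathway knockdowns the germline median had Pearson's r = -0.272 (permutation p = 0.325, adjusted 0.65) and Spearman's rho = -0.136 (permutation p = 0.628, adjusted 0.628) with the number of genome-mapped reads, and r = 0.06 without the 2 libraries farthest in depth; 4 relations were computed in this family.

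**Figure D2:**
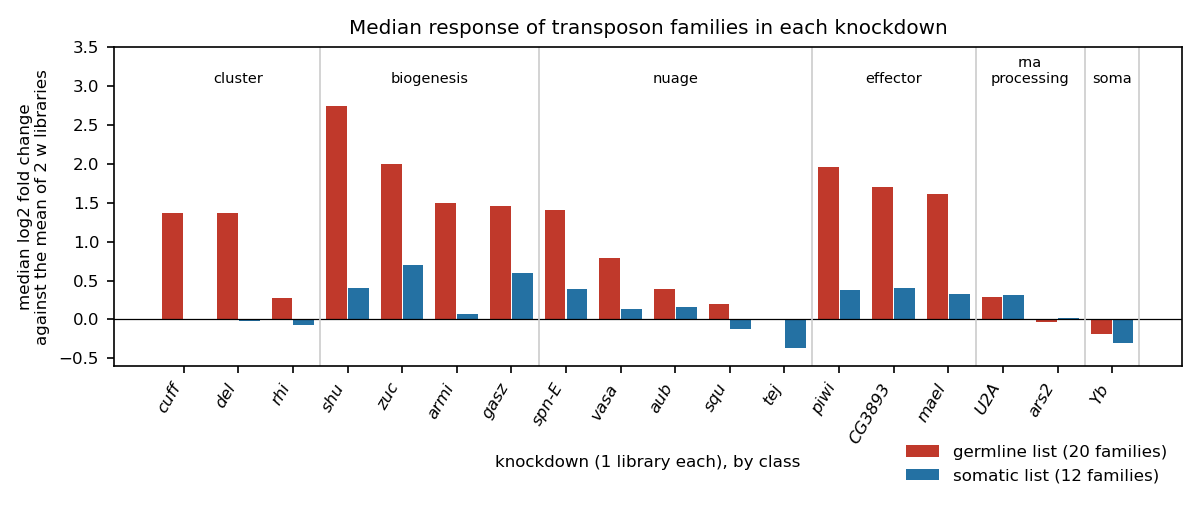
Median log2 fold change against the mean of the 2 w libraries (vertical) over the 20 germline and 12 somatic families, for each of 18 knockdowns with 1 library each (horizontal, grouped by class of the targeted gene). Bars start at 0; the germline median is 2.74 for shu and -0.19 for Yb, and the somatic median stays between -0.36 and 0.71.

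The 15 knockdowns of piRNA pathway genes were then tested as 1 group against the 2 w libraries, so that the spread is that between knockdowns of different genes. limma called 6 of 159 families, all higher. 3S18 had a log2 difference of 4.92 (SE 1.14, adjusted p = 0.0167), Burdock 4.08 (SE 0.71, adjusted p = 0.00173), blood 3.51 (SE 0.62, adjusted p = 0.00173), and diver 3.29 (SE 0.74, adjusted p = 0.0167). Of the others, 1 LTR family differed by 1.44 (SE 0.37, adjusted p = 0.0315), and R2-element, which inserts into ribosomal RNA genes, differed by 0.71 (SE 0.19, adjusted p = 0.0326). The telomeric families HeT-A and TAHRE had differences of 3.14 (SE 1.14) and 2.28 (SE 0.87) and were not called (adjusted p = 0.154 for both), although both passed when adjusted over the list alone. Of the germline list 4 of 20 families were called and 9 adjusted over the list alone, with a list median of 1.22. Of the somatic list 0 of 12 were called by limma, with 2 at an unadjusted p under 0.05 and a median of 0.20; gypsy and ZAM stood at 0.64 (SE 0.68) and 0.03 (SE 0.17). By type, 5 of 59 LTR families, 1 of 36 non-LTR families and 0 of 22 DNA transposons were called (0 of these 22 also at an unadjusted p under 0.05). All 6 calls rest on 2 controls: 3 families were called without w replicate 1 and 0 without w replicate 2. With the ovary libraries added to the controls 29 families were called (25 higher, 4 lower), and with the ars2 and U2A knockdowns added to the tested group 0.

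**Figure D3:**
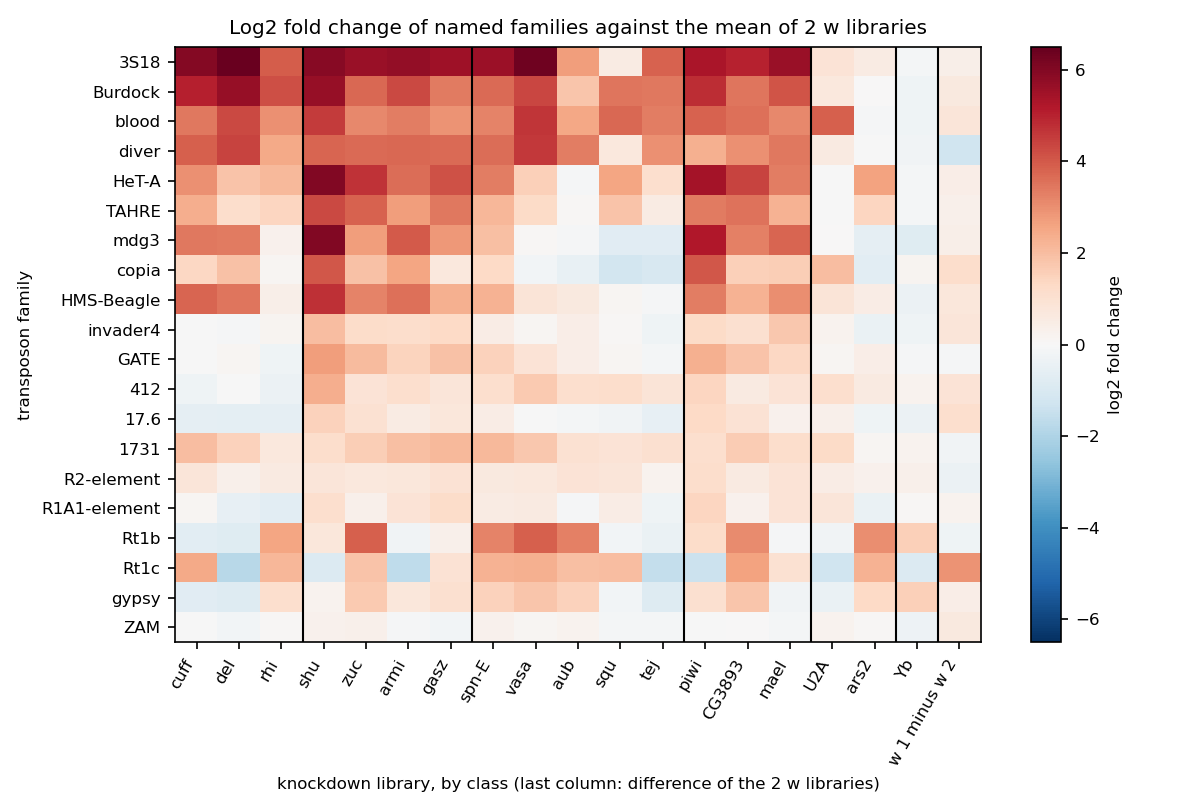
Log2 fold change of 20 transposon families (vertical) against the mean of the 2 w libraries in 18 knockdown libraries (horizontal, grouped by class), with the difference between the 2 w libraries in the last column; the colour scale runs from blue (lower) through white (0) to red (higher). 3S18 reaches 6.42 in del, HeT-A 6.02 in shu, blood 3.87 in U2A, and ZAM stays between -0.34 and 0.33.

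To ask whether the function of the targeted gene goes with the families that respond, the 15 pathway knockdowns were divided into 4 classes fixed from textbook function. These are cluster (rhi, del and cuff, which bind piRNA source loci on chromatin), biogenesis (armi, zuc, gasz and shu, which make or load piRNAs), nuage (aub, spn-E, vasa, tej and squ) and effector (piwi, CG3893 and mael, which act in nuclear silencing). The levels of the targets in these libraries were not analysed. Differences between classes can therefore not be told apart from differences in the strength of the knockdowns. In the cluster class 15 families were lower than in the other classes by limma, with 39 at an unadjusted p under 0.05. The median difference over all 159 families was -0.25 here, so these calls sit on a general shift to lower values. That median was -0.11 for the nuage, 0.18 for the biogenesis and 0.19 for the effector class. GATE had a log2 difference of -1.53 (SE 0.33, adjusted p = 0.0178), R1A1-element one of -1.04 (SE 0.28, adjusted p = 0.0345) and Idefix one of -1.01 (SE 0.30, adjusted p = 0.0495). Against w GATE stood at -0.06 ± 0.20 (SD, n = 3) in the cluster class and at 2.04 ± 0.53 (SD, n = 4) in the biogenesis class. The other 12 were invader4, Rt1a, accord2, diver2, Cr1a, X-element, Circe, gypsy2, mdg1, pogo and 2 LTR families, at -1.36 (SE 0.32, adjusted p = 0.0208) and -1.15 (SE 0.25, adjusted p = 0.0178), and HeT-A, Burdock and blood were not called (-1.26 with adjusted p = 0.251, 1.06 with 0.251 and 0.08 with 0.932). Of the germline list 5 of 20 were lower (5 adjusted over the list alone), of the somatic list 1 of 12, Idefix (0 over the list alone), of LTR families 10 of 59 (14), of non-LTR families 4 of 36 (8), of DNA transposons 1 of 22, pogo (3), and of the telomeric list 0 of 2 (0 at an unadjusted p under 0.05). The lists overlap, and the called germline families and Idefix are also counted among the LTR or non-LTR families. The count of 15 was 1 without cuff, 1 without del, 2 without rhi (1 of them higher), 7 without gasz, 8 without piwi, shu, spn-E or squ, and 9 without aub or zuc, and 34 without tej. It was 3 after scaling to 1 median over families and 24 with families of melanogaster name only.

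In the nuage class 8 families were lower than in the other classes by limma, with 26 at an unadjusted p under 0.05. mdg3 had a log2 difference of -3.33 (SE 0.68, adjusted p = 0.0223), copia of -2.26 (SE 0.59, adjusted p = 0.042), HMS-Beagle of -2.21 (SE 0.56, adjusted p = 0.0399), HeT-A of -2.09 (SE 0.57, adjusted p = 0.048), gypsy12 of -1.77 (SE 0.37, adjusted p = 0.0223) and TAHRE of -1.59 (SE 0.40, adjusted p = 0.0399). HeT-A stood at 1.69 ± 1.32 (SD, n = 5) against w in this class, 4.63 ± 1.03 (SD, n = 4) in the biogenesis class, 4.40 ± 1.04 (SD, n = 3) in the effector class and 2.31 ± 0.58 (SD, n = 3) in the cluster class, whereas blood stood at 3.49 ± 0.78 in the nuage class and between 3.48 and 3.57 in the other 3. Both telomeric families were lower (both over the list alone), 5 of 20 germline families (7), 2 of 36 non-LTR families (2), 5 of 59 LTR families (7), 1 of 22 DNA transposons, Bari1 (1), and 0 of 12 somatic families (0, with 1 at an unadjusted p under 0.05). These lists overlap, and the non-LTR calls are the telomeric families HeT-A and TAHRE. The germline calls are HeT-A and TAHRE with copia, invader4 and mdg3, which are also LTR calls. The count of 8 was 4 without armi, 3 without aub, del, piwi, shu or zuc, 2 without cuff and 0 without squ, tej or vasa. It was 2 after scaling to 1 median over families. In the biogenesis class limma called 1 family, invader4, higher by 0.90 (SE 0.19, adjusted p = 0.0474) with 37 at an unadjusted p under 0.05. TAHRE stood at 1.62 (SE 0.43, adjusted p = 0.0541) and HeT-A at 1.83 (SE 0.61, adjusted p = 0.112). Of the lists, germline had 1 of 20 and LTR 1 of 59, which is invader4 in both, and adjusted over the list alone the counts were 2 telomeric, 5 germline, 4 non-LTR, 4 LTR and 1 DNA family. At an unadjusted p under 0.05 there were 2 telomeric, 3 somatic, 11 non-LTR and 4 DNA families, lists in which limma called 0. The 1 call became 0 without aub, CG3893, cuff, del, gasz, rhi, shu, squ or zuc, 6 without armi, 11 without piwi, 5 without spn-E, 3 without tej and 4 without vasa. It was also 0 without the filter and 0 after scaling to 1 median over families, 3 with a pseudocount of 10 and 9 with families of melanogaster name only. In the effector class limma called 0 families, with 19 at an unadjusted p under 0.05, and 1 without shu; HeT-A stood at 1.52 (SE 0.67, adjusted p = 0.376), and adjusted over the list alone 1 germline family was higher. At an unadjusted p under 0.05, the germline, somatic, telomeric, LTR, non-LTR and DNA lists had 5, 1, 1, 8, 5 and 3 families higher in this class.

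The germline median averaged 1.92 ± 0.60 (SD, n = 4) in the biogenesis class, 1.76 ± 0.18 (n = 3) in the effector class, 1.00 ± 0.63 (n = 3) in the cluster class and 0.56 ± 0.56 (n = 5) in the nuage class. A permutation test of the class labels on the range of these means, 1.36, gave p = 0.0664 (100000 draws), which did not pass 0.05, and the p was 0.0487 without armi, 0.0455 without gasz and 0.0264 without spn-E. Profiles over all 159 families, centred on the mean of the 15 knockdowns so that no control enters, were more alike within classes. Their mean correlation across families was 0.118 for 22 pairs of the same class and -0.119 for 83 other pairs, a difference of 0.24 with permutation p = 0.0228, which was not called without aub (0.15, permutation p = 0.0923) or vasa (0.18, permutation p = 0.0641). Nor was it called with mael moved to the nuage class (0.16, permutation p = 0.0611). Families are not independent replicates, and the permutation was over libraries.

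As a background for the control knockdown, the 2 w libraries were compared with the 2 ovary libraries. limma called 0 of 159 families, with 28 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0554. HeT-A stood at 0.57 (SE 0.20, adjusted p = 0.276), TAHRE at 0.22 (SE 0.20), blood at 0.61 (SE 0.33), gypsy at -0.28 (SE 0.24) and Burdock at -0.03 (SE 0.40). None of the germline, somatic, telomeric, LTR, non-LTR and DNA lists held a called family, and at an unadjusted p under 0.05 the numbers higher were 4, 0, 1, 9, 5 and 3. The count of 0 was 10 without w replicate 1, 12 without w replicate 2, 4 after scaling to 1 median over families and 16 with a replicate block, although replicate numbers do not pair these libraries.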

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

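The counts of families per class and the comparison of single libraries within a class were planned, and no test in this part was chosen after its result was seen.

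In the biogenesis class, the log2 difference of invader4 against w was 2.02 in the shu library, far from the other 3 libraries, of which the nearest was gasz at 1.301 and the lowest 1.17. Of 44 groups of libraries searched for such a far sample, this was the 1 found. Chance gives about 1 in 20 groups, so 1 in 44 is not more than chance gives. Without shu, no family was called in the biogenesis comparison (0 by limma), so invader4 (0.90, SE 0.19, adjusted p = 0.0474) rests on that library among others.

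Families called by limma numbered 15, 8, 1 and 0 in the cluster, nuage, biogenesis and effector classes, and these counts were not tested against each other. In the cluster class 15 families were lower than in the other classes. Of 100 splits 1, the real one, reached 15, and the highest of the other splits gave 14. This argues against chance only narrowly, since 14 is close to 15 and the share was not adjusted for the 4 classes. The 15 calls included GATE, R1A1-element and Idefix. Their count was 1 without cuff or del, 2 without rhi, 7 without gasz, 8 without piwi, shu, spn-E or squ, 9 without aub or zuc, 34 without tej and 3 after scaling to 1 median over families. In the nuage class 8 families were lower, and 4 of 100 splits were as large, the real one included. That share is small, but it was not adjusted for the 4 classes, so chance is not excluded by it. The highest of the other splits gave 26 families, several times the real count, which may reflect a structure of the libraries, and no such structure was tested. The count of 8 was 0 without squ, tej or vasa, 2 without cuff, 3 without aub, del, piwi, shu or zuc, 4 without armi and 2 after that scaling. In the biogenesis class 1 family was higher, and chance cannot be excluded, with 9 of 100 splits as large and a highest other split of 33, again many times the real count. For the effector class, where limma called 0 families (19 at an unadjusted p under 0.05), the splits are no test, because every split reaches a count of 0 (the highest other gave 5).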

How the results depend on the processing

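The fit with families of melanogaster name only was chosen after the result was seen, and the other alternatives were planned. Among the transposon families named by the rule 787 values stayed on their side of the threshold, 113 were no longer called (most often Idefix, HeT-A and HMS-Beagle) and 7 became called. Families called in neither fit, such as blood in the class comparisons, changed sign in some alternatives. Among named genes 3060 values stayed on their side of the threshold, 109 were no longer called, 52 became called and 22 reversed while called in at least 1 of the fits. Of the list tests 24 stayed and 21 calls were lost with an estimated correlation. Among summaries of single knockdowns 356 stayed within the spread of the controls and 76 moved. The cause was not tested unless given.

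Reversals in ovary minus carcass after quantile normalization were CG7082 (-0.55), AGO2 (-0.25) and RpS5a (0.16). After median-ratio scaling they were CG7082 (-0.54), AGO1 (-0.22), AGO2 (-0.78), grk (-0.52), RpL4 (-0.11), RpLP1 (-0.61) and w (-0.51), as the median of all genes moved from 0.31 to -0.29. Without carcass replicate 2, CG5508 stood at 0.26, and without carcass replicate 1 at -0.31. In embryo minus ovary, quantile normalization reversed CG31755 (0.55), loqs (0.58), TpnC41C (1.29), spn-E (0.37) and rhi (0.080), and median-ratio scaling CG31755 (0.43), loqs (0.063), spn-E (0.84), piwi (0.80), rhi (0.26) and w (0.081).

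Ovary minus OSS had 3040 genes at 2-fold or more. Replicate numbers do not pair the libraries, and with a replicate block the gene counts were 8502 for ovary minus carcass, 4566 for ovary minus OSS and 6733 for embryo minus ovary, while w minus ovary rose from 0 to 16 families (12 higher, 4 lower). The biogenesis count was 3 with a pseudocount of 10, 0 without the filter and 0 after scaling to 1 median over families. That scaling also gave 3 for the cluster class, 2 for the nuage class and 4 for w minus ovary. With families of melanogaster name only, the cluster class had 24 and the biogenesis class 9. For pathway knockdowns minus w, 29 were called with ovary added to the controls (25 higher, 4 lower) and 0 with ars2 and U2A added. With mael moved to the nuage class, the similarity difference was 0.16 (permutation p = 0.0611).

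Leaving out 1 library at a time gave 7576 to 8929 genes for ovary minus carcass, 2879 to 5596 for ovary minus OSS, and 6019 to 7273 for embryo minus ovary. For families it gave 0 to 7 for pathway minus w, 1 to 34 for cluster, 0 to 11 for biogenesis, 0 to 12 for nuage, 0 to 1 for effector and 0 to 12 for w minus ovary. The range of class means of the germline median was 1.20 to 1.58, the similarity difference 0.15 to 0.30, and the number of knockdowns with a germline median of at least 2-fold 9 to 10. Depth limits the transposon values most for gasz and CG3893, at 2026093 and 2429481 genome-mapped reads.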

Other observations

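Tests on ovary tissue left in the carcass, on misassigned reads, on scaling, on values listed at 0, on loss of the pathway and on fly stocks were chosen only after the result was seen, and the comparison of libraries of like depth was added after the rank correlation with depth was known. The families in the next paragraphs outside the rule for names were chosen after their values were seen.

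Knockdowns outside the 15 pathway genes also had raised families, which were raised in 1 or more pathway knockdowns as well (copia 4577 and Tirant 194 in piwi, gypsy 693, Fw2 359 and Rt1b 2904 in vasa). After knockdown of U2A, a splicing factor gene, blood reached 4467 (401 and 232 in the w libraries), copia 1092 (404 and 185) and Tirant 308 (92 and 87), while 3S18 stood at 232 and HeT-A at 130. After knockdown of ars2, whose product acts with the proteins that bind RNA caps, HeT-A reached 805 (151 and 112) and Rt1b 1620 (179 and 221), while blood stood at 294 and Burdock at 64. After knockdown of Yb, Fw2 reached 466 (43 and 61), Damb_P-element_T 286 (51 and 65) and gypsy 578 (226 and 170), while blood stood at 253. These are single libraries without a replicate, so the rises cannot be credited to the loss of the targeted gene. fs(1)Yb acts in ovarian somatic cells and nos-GAL4 in the germline, so the rises in the Yb library may be differences between single libraries. Rt1b and gypsy also went together over all 20 knockdown libraries (Spearman's rho = 0.93), as described below.

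Among the pathway knockdowns, squ left 3S18 at 176 (141 and 107 in the w libraries) and mdg3 at 80, with blood at 4101 and HeT-A at 788. aub left HeT-A at 122 with Burdock at 229 and diver at 2029 (129 and 322). The I-element, a non-LTR retrotransposon of hybrid dysgenesis, was highest in the shu library at 838 (155 and 100) and between 64 and 292 in the other pathway libraries. Dnet_R1A, an element of the R1 kind that inserts into ribosomal RNA genes, was between 51 and 162 in cuff, del, gasz, mael, piwi, shu, squ, Yb and both w libraries and between 8 and 14 in the others and in ovary. It differed between w and ovary by 2.70 (SE 0.44, adjusted p = 0.0554 by limma), in libraries that had been depleted of ribosomal RNA.

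The first pattern is that germline transcripts were present in the carcass, where 28 maternal germline genes had a median of 6.03% and 7.31% of their ovary level in the 2 libraries (quartiles 4.36% to 14.6%) and eggshell genes 3.94% and 3.63%. Of 1222 genes at an ovary FPKM of 100 or more, 0 (0%) lay under 1% of it in both carcass libraries. Ovary tissue left in the carcass is a candidate explanation, although msd1, at 85.6 in ovary, was listed at 0 in both. The share of 0% cannot decide it, because carcass cells may express many of these 1222 genes themselves. Reads misassigned between libraries in every direction are argued against as the whole cause, since 148 of 965 genes abundant in carcass (15.3%) lay under 1% in both ovary libraries. Muscle genes, however, stood in ovary at a median of 4.46% of their carcass level, so a contribution of such reads is not excluded. Mature eggs in the carcass stay open. Over the maternal genes the SD of the log2 difference was larger by 1.303 against embryo (2.73) than against ovary (1.42), but the planned reading of this value was wrong, because no eggs were profiled and decay of maternal RNA in the embryo would widen that spread as well. Low expression of these genes in carcass cells was not tested and stays open.

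The second pattern is that 17 of 29 maternal germline genes fell between ovary and embryo, among them alphaTub67C, gnu and nos. Of all 11488 genes tested, 5150 were called lower in embryo as deposited. camera did not call this list against other genes (adjusted p = 0.862, and 0.964 with an estimated correlation). A fall particular to maternal germline genes was thus not shown. Scaling is argued against as the whole cause, since at least 16 fell under both other scalings. Failed estimates listed at 0 are argued against too, since only 2 of the 17, stil and png, had a 0 in an embryo library. Estimates that came out too low without reaching 0 were not tested. Transcript length is argued against as well: the log2 change rose by 0.481 per doubling of length over 7321 genes, and after this trend was removed 15 of 15 members at -1 or below, 100%, stayed there (median -3.58 before and -3.69 after). GC content was not analysed here. Decay of maternal RNA, selective loading into the egg and a contribution of younger egg chambers to the ovary are possible biological explanations that were not tested.

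The third pattern is that Rt1b, a non-LTR retrotransposon, was between 1189 and 2904 in 7 of 20 knockdown libraries (vasa, zuc, aub, spn-E, CG3893, ars2 and rhi) and between 114 and 576 in the other 13, which include both w libraries. Depth is argued against, since its Spearman's rho with genome-mapped reads was -0.21 (permutation p = 0.38, adjusted 0.588; Pearson's r = -0.128, permutation p = 0.599, adjusted 0.799) and 18 of 190 pairs of libraries within 10% in depth differed by a median log2 of 2.12 against 1.69 over all pairs, or 125%. Loss of the pathway is argued against as the whole cause, since 4 knockdowns with a germline median of at least 2-fold (armi, cuff, del and mael) had Rt1b at or below the higher w library. A difference between fly stocks that several families share may contribute: Rt1b went with gypsy, a family of another type, over all 20 libraries (Spearman's rho = 0.93, permutation p = 1e-05, the smallest these draws can give) and also within the 7 high libraries (rho = 0.786, permutation p = 0.0486; r = 0.793) and the 13 others (rho = 0.853, permutation p = 0.00043; r = 0.847). The labels name no stock, and apart from w each knockdown has 1 library, so that in those stock and library preparation cannot be told apart.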
